A study of Bos taurus with 18 samples.

How the data were processed

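RNA sequencing libraries of 18 bovine samples were analysed, 3 of blastocysts, 3 of trophectoderm, 2 of bTSC and 2 on each of days 2, 3, 4, 5 and 6 of differentiation. Per the labels' protocols, RNA was extracted with an RNeasy micro kit and cDNA was made with the Smart-seq2 v4 kit, in the same words for each sample. Per the submitters' processing notes, Salmon, edgeR and the genome build ARS-UCD1.2 were used; their roles, versions and the annotation are not given in the sources used here. The values are read counts per gene, which the authors deposited as whole numbers not scaled to library size; they may be estimated counts that the authors rounded. The table had 34072 rows, each with a gene identifier, of which 6677 had no count in any library and 0 named no gene. Of the identifiers, 30725 were found in the reference table of gene names, which is of assembly ARS-UCD2.0, so no coordinates are printed. A symbol stood on more than 1 row in 122 cases, and genes were followed by identifier. This kind of cDNA does not keep strand, so reads of overlapping or antisense genes cannot be told apart, and reads of near-identical gene copies may be divided between them.

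Groups and replicate numbers were taken from the sample labels, and the tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. Genes were filtered with edgeR's filterByExpr by group (minimum count 10, minimum total 15), libraries were scaled by TMM, and edgeR's quasi-likelihood F test was run with Benjamini-Hochberg adjustment at 0.05. The 8 blastocyst, trophectoderm and bTSC libraries shared 1 fit, with a common biological coefficient of variation of 0.516. The 12 cultures shared another (0.0982), which gave the 5 day comparisons and a test of any change over the days. The trend was the slope of log2 expression per day over the 10 libraries of days 2 to 6 (0.211). Day entered that fit as a number, so its value takes in departures from a straight line beside the spread between replicates. CPM were computed from the counts with TMM-scaled library sizes within the fit a comparison belongs to, so that a group's CPM differ slightly between fits. A fold against a group with 0 counts is a lower bound set against 3 counts over that group, and covers counting error only, since reads without molecular identifiers are not independent molecules. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

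Named genes were up to 6 higher and 6 lower genes with the largest log2 fold change among those past the threshold, with a mean of 20 CPM or more in the higher group, no overlap between groups and a gene symbol (3 and 3 for the trend). To these were added up to 4 members past the threshold and up to 2 others of each list, and 25 genes of trophoblast, pluripotency, endoderm, imprinting and cell division named whether or not they passed. Of 30 gene lists, 28 had 4 or more members in the counts, and 27 with at least 4 tested members were tested in each comparison by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. A list of mitochondrial genes had no member in the counts. With camera's estimated correlation, 1 of 10 list calls held in bTSC against trophectoderm, 1 of 9 in bTSC against blastocysts and 4 of 15 on day 2. None held of the 2 in trophectoderm against blastocysts, the 18, 17, 14 and 12 on days 3, 4, 5 and 6, and the 2 in the trend.

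Depth differed between groups. Blastocyst libraries held 6534656, 11308529 and 11469146 counts, so that 3 counts came to 0.459, 0.265 and 0.262 CPM, against 0.0707 to 0.138 CPM in trophectoderm and 0.073 to 0.106 CPM in cultures. The procedure was tested on simulated data with the real library sizes. Each gene was set at its mean over all libraries of the fit, and 200 well-counted genes were changed. Each gene was given the same dispersion in all libraries of a fit. Real replicates differed more in the embryo groups (chi-square per degree of freedom 30.3 to 157) than in bTSC (8.55). The simulated shares of false calls may therefore not hold where the spread differs between groups. Far more genes were called in the real comparisons: 3206 in trophectoderm against blastocysts, 9308 in bTSC against trophectoderm and 7565 on day 6. Recovery and false calls can depend on how many genes change, so the simulated shares may not hold there either. In trophectoderm against blastocysts edgeR recovered 7% of 2-fold and 54% of 4-fold changes (16397 genes), with 6.15% false among its calls. The shares were 4% and 51% in bTSC against trophectoderm (16350 genes, 6.78% false), 90% and 99% on day 6 (15879 genes, 4.69% false), 89% and 100% for any day (15868 genes, 4.23% false) and 64% and 97% for the trend (15751 genes, 6.94% false). These shares did not follow depth or replicate number alone, since the spread between libraries was wider in the embryo fit (0.516 against 0.0982 in cultures). DESeq2 gave 10.2 to 41.8% false among calls in the same simulations. Replicates of a group differed by more than sampling noise in each pair (chi-square per degree of freedom 5.75 to 157) and none held identical values.

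Alternatives were DESeq2's size factors, no filter and a stricter filter (5 CPM in 2 libraries), DESeq2, limma-voom with quality weights, counts thinned to the smallest library, all 18 libraries in 1 fit, a fold threshold in addition, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Leaving out 1 of 2 libraries leaves the other without a replicate, and the fit then assumes that it varies like the other groups. Added after seeing the data were fits without the 18S ribosomal RNA gene and a related pseudogene, a trend over days 3 to 6, and trophectoderm against blastocysts without genes more than 4 times higher in 1 blastocyst library than in the next.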

Results

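RNA abundance was measured by sequencing in 18 bovine libraries. They came from blastocysts produced in vitro (day 7, n = 3), isolated trophectoderm (n = 3), undifferentiated bovine trophoblast stem cells (bTSC, n = 2), and the same kind of cell on days 2, 3, 4, 5 and 6 of differentiation (n = 2 per day). Trophectoderm is the outer epithelium of the blastocyst, from which the placenta forms. The labels do not give the day on which trophectoderm was isolated. Total counts per library were 6534656 to 11469146 in blastocysts, 21689960 to 42431608 in trophectoderm and 28276825 to 41102667 in the 12 cultures, with 16074 to 20193 genes counted at least once. The 18S ribosomal RNA gene took 2.92 to 6.14% of counts in blastocysts, 0.561 to 0.822% in trophectoderm and 0.082 to 0.261% in cultures. The labels do not say whether replicates were separate cultures or embryo pools, so p-values measure the spread between these samples, which may be technical. Expression is given as mean CPM (counts scaled by library size) ± SD, and changes as log2 fold changes with their standard errors (SE).

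**Figure D1:**
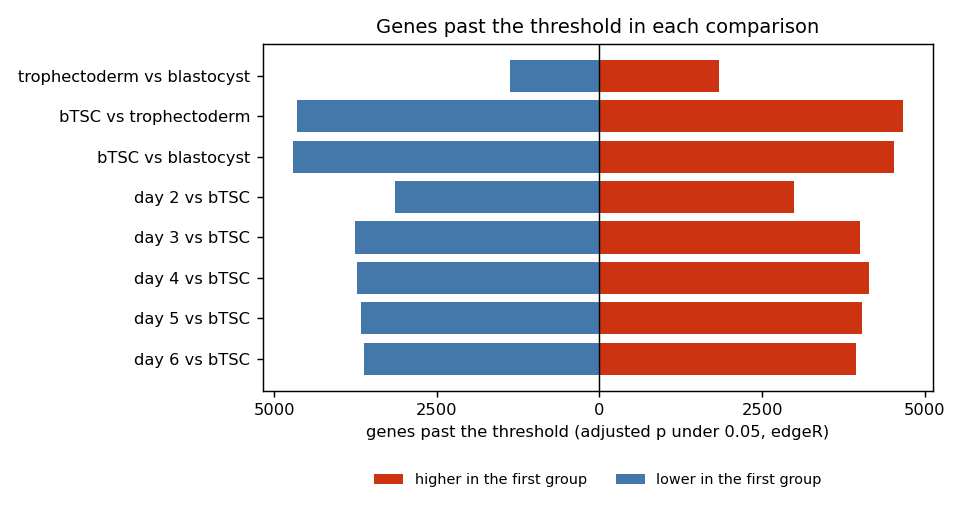
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test (axis: genes), split into higher and lower, for each comparison. Trophectoderm and blastocyst differed in 3206 genes, bTSC and trophectoderm in 9308, and day 6 and bTSC in 7565.

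To ask how the outer layer differs from the whole embryo, which also holds the inner cell mass, trophectoderm was compared with blastocysts. Trophectoderm had more RNA of CDX2 (gene ID 618679), a transcription factor of the trophectoderm lineage, at 17.5 ± 1.48 against 4.79 ± 1.21 CPM (log2 fold change 1.88, SE 0.216). KRT8 and KRT19, keratins of simple epithelia, were higher by 1.93 (SE 0.147; 5561 ± 863 against 1462 ± 35 CPM) and 2.68 (SE 0.258). HSD3B1, an enzyme of progesterone synthesis, rose from 12.5 ± 4.89 to 145.3 ± 44.5 CPM (3.52, SE 0.349). PDGFRA, a receptor of primitive endoderm, was at 1.23 ± 0.964 against 95.9 ± 22.1 CPM (-6.22, SE 0.551; -7.11 without trophectoderm replicate 1 and -6.96 in limma-voom). OTX2, a transcription factor of epiblast, was at 19.1 ± 7.83 against 219.7 ± 33.6 CPM (-3.53).

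In edgeR's quasi-likelihood test, 3206 of 18039 genes passed an adjusted p of 0.05, 1833 of them higher in trophectoderm and 1373 lower. Changes beyond 2-fold numbered 1382 and 930. The count fell to 1752 without blastocyst replicate 6 and to 2086 without blastocyst replicate 5, and was 6158 when all 18 libraries shared 1 fit. The 2 bTSC libraries also entered the spread of the main fit. They were closer to each other (r = 0.996 over log2 CPM) than libraries within the embryo groups (0.931 to 0.968). These calls thus lean in part on the spread of cultures. The adjusted p in edgeR was 0.000961 for CDX2, 0.000221 for KRT8, 0.000446 for KRT19 and 0.000505 for both HSD3B1 and PDGFRA.

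Among the other genes with large increases, LY6E, a membrane-anchored surface protein, rose by 3.55 on the log2 scale, the actin-binding protein gene CNN2 by 3.43 and KLHL40 by 3.60. CYP11A1, which makes pregnenolone from cholesterol, rose by 3.65, and by 2.95 without trophectoderm replicate 3. DDIT4L, an inhibitor of mTOR signalling, rose by 4.05, and by 3.07 without the same library. Of 15 steroid synthesis genes 4 rose and 1 fell, also adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.221). PAG2, a pregnancy-associated glycoprotein, rose from 24.9 ± 9.47 to 66.2 ± 15.3 CPM (1.40, SE 0.299). PAG, IFNT and TKDP genes have near-identical copies, so the division of reads within each family is uncertain.

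Of 22 trophoblast transcription factor genes 3 rose and 4 fell (5 and 5 adjusted over the list alone), and camera gave an adjusted p of 0.534. MSX2 rose by 2.14 beside CDX2, whereas GCM1, a regulator of syncytium formation, fell by 5.50, and fell by 6.23 without trophectoderm replicate 2. GATA2 fell by 0.89, a call that ended without blastocyst replicate 5 (-0.77) or replicate 6 (-0.85). TFAP2C fell by 0.67, and its call ended in 6 of the 8 fits that left out a library, with values of -0.51 to -0.67 when blastocyst replicate 5 or 6, trophectoderm replicate 1 or 2, or either bTSC library was left out, and without the 18S RNA gene (-0.58). GATA3 (-0.21), TEAD4 (0.65), ELF5 (1.30), PAG11 (-0.05), IFNT2 (2.16) and MKI67 (-0.61) did not pass in edgeR, but 3 of them did in other fits. TEAD4 passed in DESeq2 (0.62), in limma-voom (0.59), with a stricter filter (0.67), with all 18 libraries in 1 fit (0.78), without the 18S RNA gene (0.76) and without trophectoderm replicate 2 (0.85). IFNT2 passed in DESeq2 (2.12), in limma-voom (2.38), after thinning (2.35), with all 18 libraries (2.25) and without trophectoderm replicate 1 (2.68). MKI67 passed in DESeq2 (-0.66), with its size factors (-0.65), after thinning (-0.74), with all 18 libraries (-0.51) and without trophectoderm replicate 3 (-0.74). KRT18 rose by 0.72, and did not pass without blastocyst replicate 6 (0.67). XIST, the RNA of X inactivation, was at 176.4 ± 45.3 against 77 ± 14.1 CPM, and its call ended without any 1 of the 3 blastocyst libraries or without trophectoderm replicate 2 or 3 (log2 fold changes of 1.05 to 1.31).

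Genes of pluripotency moved both ways, with 3 rising and 3 falling among 19 (4 and 5 adjusted over the list alone; camera adjusted p = 0.534). POU5F1 (gene ID 282316), a core pluripotency factor, was at 766.8 ± 356 CPM in trophectoderm and 260.1 ± 27.1 in blastocysts (1.56, SE 0.315; adjusted p = 0.0101 in edgeR). ZFP42 rose by 2.96 and DPPA2 by 2.90. NANOG was lower (-2.25, SE 0.575), but the call ended when blastocyst replicate 5 (-1.63), blastocyst replicate 6 (-2.25) or any 1 of the trophectoderm libraries (-2.05 to -2.36) was left out. SOX2 was -1.12 and did not pass. Among 15 genes of hypoblast, the layer that gives yolk sac endoderm, 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.33), and GATA6 fell from 649.6 ± 36.5 to 300.2 ± 74.4 CPM (-1.11). Of 16 genes of the FGF and ERK pathway 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.33), among them the feedback inhibitors SPRY2 (-3.08) and SPRY4 (-2.84).

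Both metabolic lists below passed in camera with its preset correlation and neither did with an estimated one. Of 22 cholesterol synthesis genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with an adjusted p = 0.0101 in camera and an adjusted p = 0.735 with an estimated correlation. IDI1 rose by 1.28, EBP by 1.44 and FDPS by 1.16. Without blastocyst replicate 1 the camera adjusted p was 0.126. Of 19 genes of oxidative phosphorylation 6 rose and 1 fell (8 and 2 adjusted over the list alone), including SDHB (1.42), COX5A (1.28) and CYC1 (1.34). The camera adjusted p was 0.0187, or 0.735 with an estimated correlation, and it was 0.161 without blastocyst replicate 5 and 0.102 without trophectoderm replicate 1.

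The largest decreases by the fixed rule also held genes at high counts in blastocyst replicate 1. OOSP2, a gene of the oocyte, had 270.4 ± 428 CPM in blastocysts and 1.17 ± 0.391 in trophectoderm (-7.81, and -4.30 without blastocyst replicate 1). CCDC181 went from -6.02 to -3.45 without that library. BCAR4 (-4.82), ACSM4 (-4.30) and KPNA7 (-3.90) did not pass without it. The calls of OOSP2 and CCDC181 also ended without trophectoderm replicate 3 (-7.55 and -5.99), and that of OOSP2 without trophectoderm replicate 2 (-7.70). Those of BCAR4 and KPNA7 ended without blastocyst replicate 6 or trophectoderm replicate 1 or 3 too, and that of KPNA7 without trophectoderm replicate 2, with values of -6.84 to -8.06 and -5.17 to -6.18. None of these 5 genes passed in limma-voom (BCAR4 at -6.73 and OOSP2 at -5.38), and BCAR4 did not in DESeq2 (-7.59).

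**Figure D2:**
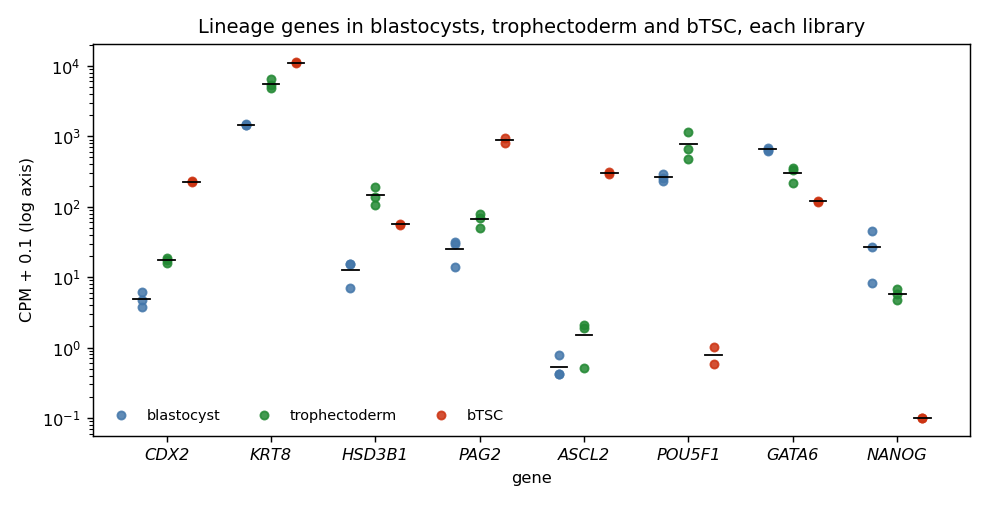
CPM (log axis, with 0.1 added) of 8 lineage genes in each blastocyst, trophectoderm and bTSC library; points are libraries and bars are means. CDX2 and KRT8 were higher in trophectoderm than in blastocysts and highest in bTSC, and POU5F1 fell from 766.8 CPM in trophectoderm to 0.697 in bTSC.

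To place the cultured cells against the lineage they are named for, bTSC were compared with trophectoderm. CDX2 was at 227.2 ± 1.73 CPM in bTSC and 17.5 ± 1.48 in trophectoderm (3.70, SE 0.227; adjusted p = 3.59e-06 in edgeR). ASCL2, an imprinted transcription factor of trophoblast progenitors, was at 303.8 ± 12.5 against 1.41 ± 0.876 CPM (7.71, SE 0.518). POU5F1 was at 0.697 ± 0.295 against 766.8 ± 356 CPM (-10.09, SE 0.569; adjusted p = 2.66e-06 in edgeR; -10.82 after thinning). PAG2 rose from 66.2 ± 15.3 to 874.1 ± 86.7 CPM (3.72), and PAG11 was at 250.7 ± 22.3 CPM in bTSC and 0.306 ± 0.53 in trophectoderm. The log2 fold change of PAG11 was 9.36, but 15.35 without trophectoderm replicate 1 and 12.84 in limma-voom. MKI67, a protein of cycling cells, rose from 22.8 ± 5.29 to 240.8 ± 25.5 CPM (3.40), and MCM2, part of the replicative helicase, by 3.07.

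Of 18039 genes, 9308 passed in edgeR, 4664 higher in bTSC and 4644 lower. Some of the largest changes were in genes with 0 counts in a group, for which a lower bound was set against a floor of 3 counts over that group. Such a bound covers counting error only. H19, an imprinted long non-coding RNA, was at 543 ± 68.4 CPM in bTSC and was at least 15000-fold higher. FAM129B was at least 9040-fold higher, CGA, the alpha subunit of glycoprotein hormones, at least 5280-fold, PLA2G3 at least 4110-fold, the collagen gene COL5A1 at least 3610-fold and NPR1 at least 2730-fold. SPIC (419.6 ± 241 CPM in trophectoderm) was at least 9220-fold lower and DPPA3, a maternal and germ cell factor, at least 8400-fold. SLC1A3 was at least 1810-fold lower, DNAH8 1460-fold, MAEL 1300-fold and COX7B2 1200-fold at the least. NANOG and SOX2 had 0 counts in bTSC and were at least 125-fold and 169-fold lower.

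Of 22 trophoblast transcription factor genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a camera adjusted p = 0.00276 and an adjusted p = 0.302 with an estimated correlation. GATA2 rose by 2.50, and TFAP2C (0.00) and TEAD4 (0.29) did not pass, TEAD4 doing so in limma-voom (0.42) and without trophectoderm replicate 1 (0.52). GATA3 was higher by 0.66 (adjusted p = 0.0139 in edgeR), and did not pass without bTSC replicate 1 (0.69) or replicate 2 (0.65). ELF5 was at 3.40 and narrowly missed the threshold (adjusted p = 0.0518 in edgeR). It passed in DESeq2 (3.44), in limma-voom (3.99), with DESeq2's size factors (3.45), with no filter (3.42), with a stricter filter (3.29), after thinning (3.05) and with all 18 libraries in 1 fit (3.43). It also passed without trophectoderm replicate 1 (2.83) or replicate 3 (5.06). Epithelial keratin and junction genes rose in 13 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000721, adjusted p = 0.302 with an estimated correlation). KRT7 rose by 5.43, the adhesion protein gene CDH1 by 4.24 and the desmosome gene DSP by 4.89. KRT8 rose by 1.00 and KRT18 by 0.73, the latter lost without bTSC replicate 2 (0.69).

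Of 19 pluripotency genes 3 rose and 13 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.000733, adjusted p = 0.302 with an estimated correlation). ZFP42 fell by 3.42, whereas LIN28A, an RNA-binding protein of early cells, rose by 4.73. All 4 tested genes of the list of ancient pregnancy-associated glycoproteins rose, also adjusted over the list alone (camera adjusted p = 0.0263, adjusted p = 0.333 with an estimated correlation). That list held PAG2, PAG8, PAG10, PAG11 and PAG12 in the counts, and the other listed PAG genes were placed with those of binucleate cells. PAG12 was at least 378-fold higher, and PAG8 was at 20.8 ± 0.121 against 0.212 ± 0.366 CPM, a call that DESeq2 did not make. The log2 fold change of PAG8 was 6.69, and 11.9 without trophectoderm replicate 2. These PAG directions held with DESeq2's size factors. IFNT3, an interferon of the bovine trophoblast, fell by 4.63, and fell by 4.03 without trophectoderm replicate 3. IFNT2 fell by 3.71, fell by 3.06 without that library, and did not pass without bTSC replicate 1 (-3.61). HSD3B1 fell by 1.37, and did not pass without bTSC replicate 1 (-1.40) or replicate 2 (-1.34). CYP11A1 (0.85) did not pass, and passed without trophectoderm replicate 3 (1.63).

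Of 19 genes of glycolysis and hypoxia 16 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 8.02e-07, adjusted p = 0.049 with an estimated correlation). PKM rose from 324.7 ± 27.9 to 4088 ± 197 CPM (3.65) and ENO1 by 3.10. Oxidative phosphorylation genes rose in 2 and fell in 12 of 19 cases (2 and 13 adjusted over the list alone; camera adjusted p = 0.000381, adjusted p = 0.531 with an estimated correlation). NDUFA4 went from 2027 ± 184 to 65.8 ± 2.36 CPM (-4.95) and CYCS, cytochrome c, from 1358 ± 240 to 31.4 ± 1.86 CPM (-5.43). Of 21 matrix protease and integrin genes 15 rose and 4 fell (16 and 4 adjusted over the list alone; camera adjusted p = 0.000733, adjusted p = 0.302 with an estimated correlation). SREBF2, a regulator of sterol synthesis, rose by 5.02 and TET1, which oxidises methylated cytosine, fell by 3.15. XIST was at 176.4 ± 45.3 CPM in trophectoderm and had 4 counts in the 2 bTSC libraries together. The sex of the embryos and of the cultured cells was not among the sample attributes used, so this difference cannot be assigned to culture. SOX17, an endoderm factor, was at 59.4 ± 1.39 against 0.356 ± 0.353 CPM, and GATA6 fell by 1.34.

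Immediate early genes, which respond to handling and dissociation, moved with these groups, 11 of 14 rising and 1 falling, also adjusted over the list alone (camera adjusted p = 0.00481, adjusted p = 0.251 with an estimated correlation). Markers of mesenchyme rose in 6 and fell in 4 of 13 cases and did not pass (camera adjusted p = 0.583).

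Against whole blastocysts, bTSC differed in 9232 of 18039 genes, 4523 higher and 4709 lower in edgeR. CDX2 was higher by 5.59 (SE 0.251), ASCL2 by 9.54, KRT7 by 5.11 and KRT8 by 2.93. PAG2 rose by 5.13, from 24.9 ± 9.47 to 874.1 ± 86.7 CPM, and MKI67 by 2.79. POU5F1 fell by 8.53 (-9.30 after thinning). H19 was at least 5920-fold higher, IRX3 1430-fold, the cyclin gene CCND1 1150-fold, MFAP2 886-fold, SERPING1 871-fold and TEDC1 736-fold at the least. DPPA3 was at least 14400-fold lower, BTG4 12800-fold, SPIC 7050-fold, OOSP2 5940-fold, the receptor gene KIT 3220-fold and SLC1A3 2510-fold at the least. BTG4 (583 ± 748 CPM) and OOSP2 (270.4 ± 428 CPM) were highest in blastocyst replicate 1, at 1433 and 764.7 CPM, against 24.6 and 12.5 CPM in replicate 5 and 291.7 and 34 CPM in replicate 6.

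Of the gene lists, glycolysis and hypoxia rose in 14 of 19 cases with 0 falling, also adjusted over the list alone (camera adjusted p = 7.9e-10, adjusted p = 0.0213 with an estimated correlation), PKM by 4.16 and ENO1 by 4.43. Cholesterol synthesis genes rose in 15 and fell in 1 of 22 cases, also adjusted over the list alone (camera adjusted p = 0.000679, adjusted p = 0.467 with an estimated correlation). SREBF2 rose by 4.76 and DHCR24, which makes cholesterol from desmosterol, by 6.87. NDUFA4 (-4.52) and CYCS (-5.24) fell. XIST was at 77 ± 14.1 CPM in blastocysts against 4 counts in bTSC, and the limit on sex given above applies here too. Both embryo comparisons share the bTSC libraries, so their calls are not independent.

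To follow differentiation to its last sampled day, day 6 cultures were compared with bTSC. HAND1, a transcription factor of differentiating trophoblast, rose from 5.03 ± 0.14 to 148.1 ± 10.8 CPM (4.88, SE 0.105; adjusted p = 5.15e-18 in edgeR). TKDP4, a trophoblast Kunitz domain protein, rose from 61.6 ± 11.3 to 1467 ± 157 CPM (4.57, SE 0.11), and PAG11 from 246.9 ± 21.5 to 1612 ± 9.39 CPM (2.71, SE 0.0693). ASCL2 fell from 299.2 ± 11.8 to 91.8 ± 0.946 CPM (-1.71, SE 0.0933). BNIP3, a mitophagy receptor induced by hypoxia, fell from 199.7 ± 6.78 to 10.1 ± 1.5 CPM (-4.31, SE 0.114; adjusted p = 1.29e-16 in edgeR).

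In edgeR 7565 of 16343 genes passed at day 6, 3944 rising and 3621 falling, with 1252 and 1047 of them beyond 2-fold. When all 18 libraries shared 1 fit, 1898 passed. That fit ended the calls of CDX2, GATA3, TFAP2A, TFAP2C, ELF5, KRT18, HSD3B1, IFNT2, IFNT3, PAG10, MX1, VIM, H19 and DNMT3B at day 6 (values of -2.16 to 2.53).

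PRSS12, a secreted serine protease, rose by 5.13, the cytokine IL34 by 4.42, the connexin GJB6 by 4.22 and thrombospondin THBS1 by 4.03. RAB17, a GTPase of epithelial trafficking (-4.12), the peptide hormone gene ADM (-4.03) and RDH12 (-3.95) fell, as did DDIT4 and PIK3IP1, inhibitors of mTOR and PI3K signalling (both -3.56). Of 5 ancient pregnancy-associated glycoprotein genes 5 rose, also adjusted over the list alone (camera adjusted p = 1.16e-12, adjusted p = 0.0992 with an estimated correlation). PAG2 rose by 1.64, PAG12 by 2.75 and PAG10 by 2.45, and these directions held with DESeq2's size factors. IFNT2 rose by 1.35 and IFNT3 by 2.16. Of 16 interferon-stimulated genes 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.159 with an estimated correlation), among them ISG15 (3.14) and the antiviral GTPase MX1 (2.51).

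Trophoblast transcription factors divided, with 9 of 21 rising and 8 falling (10 and 8 adjusted over the list alone; camera adjusted p = 0.269). TFAP2A rose by 1.09 and TFAP2C by 0.43, and KLF5 (-1.14), GATA2 (-0.74), CDX2 (-0.43) and ELF5 (-2.16) fell. GATA3 was higher by 0.21, a call that ended without bTSC replicate 1 (0.19) or day 6 replicate 1 (0.13). TEAD4 (0.06), KRT8 (0.01), SOX17 (0.16) and MKI67 (0.02) did not pass. KRT18 (-0.25), VIM (-1.59), GATA6 (-1.10) and H19 (-0.74) fell. Of 15 steroid synthesis genes 6 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.896). HSD3B1 rose by 0.72, HSD17B1 by 2.31 and CYP17A1 by 1.57.

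Matrix protease and integrin genes rose in 15 and fell in 5 of 21 cases, also adjusted over the list alone (camera adjusted p = 4.91e-06, adjusted p = 0.159 with an estimated correlation). Targets of the Hippo pathway rose in 8 and fell in 1 of 12 cases, also adjusted over the list alone (camera adjusted p = 0.000403, adjusted p = 0.134 with an estimated correlation). Genes of nutrient and lipid transport rose in 11 and fell in 5 of 18 cases (11 and 6 adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.0992 with an estimated correlation). Glycolysis and hypoxia genes fell in 16 and rose in 3 of 19 cases, also adjusted over the list alone (camera adjusted p = 1.65e-14, adjusted p = 0.123 with an estimated correlation), with GAPDH at -1.38. Oxidative phosphorylation genes fell in 18 of 19 cases with 0 rising, also adjusted over the list alone (camera adjusted p = 1.18e-05, adjusted p = 0.159 with an estimated correlation). Cholesterol synthesis genes fell in 14 and rose in 4 of 22 cases (15 and 4 adjusted over the list alone; camera adjusted p = 3.13e-05, adjusted p = 0.159 with an estimated correlation), with INSIG1 at -1.72 and HMGCS1 at -0.99. DNA methylation enzyme genes fell in 4 and rose in 1 of 8 cases, also adjusted over the list alone (camera adjusted p = 0.00721, adjusted p = 0.159 with an estimated correlation), with DNMT3A at -1.64 and DNMT3B at -1.09.

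Beside these groups, all 20 ribosomal protein genes tested fell at day 6, also adjusted over the list alone (camera adjusted p = 3.58e-14, adjusted p = 0.159 with an estimated correlation), with RPLP0 at -0.94. Mesenchyme and fibroblast markers rose in 5 and fell in 2 of 12 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.00367, adjusted p = 0.123 with an estimated correlation). Of 24 listed genes of binucleate cells in the counts, 2 were tested in the cultures and 0 passed at day 6. The placental lactogen gene CSH2 and the prolactin-related gene PRP1 had 0 counts in every group, and PAG1 had 2 counts in blastocysts and 0 elsewhere. XIST had 0 to 6 counts per culture group and NANOG 0 to 7, too few to test in the cultures.

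**Figure D3:**
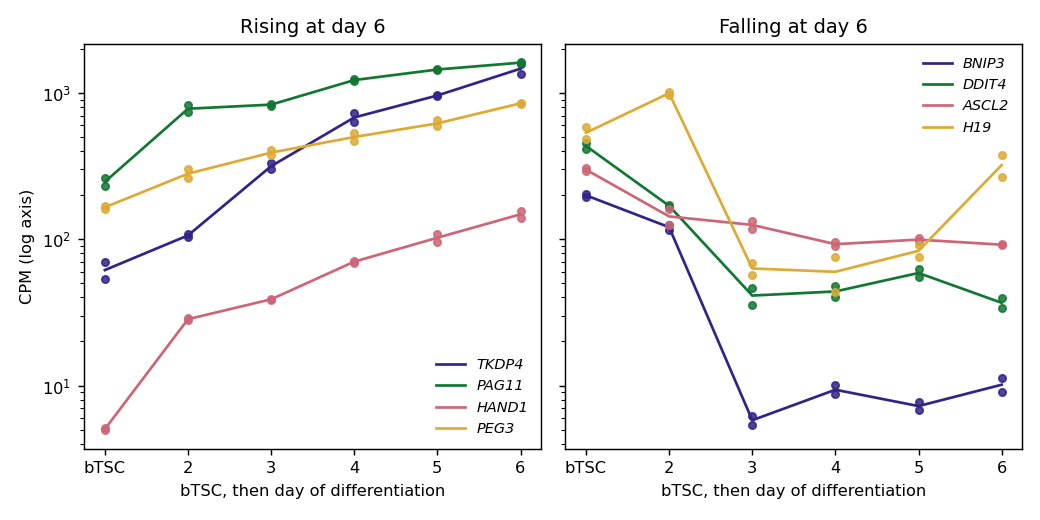
CPM (log axis) of 8 genes in bTSC and on days 2 to 6 of differentiation; points are libraries and lines join the group means. HAND1 went from 5.03 to 148.1 CPM and BNIP3 from 199.7 to 10.1 CPM, while H19 was at 997 CPM on day 2 and 63.1 CPM on day 3.

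By day 2 of differentiation HAND1 had risen by 2.50 (SE 0.106), PAG2 by 1.70 and PAG11 by 1.66, and ASCL2 had fallen by 1.06. TIMP3, an inhibitor of matrix proteases, rose by 2.11, and the integrins ITGA2 and ITGA6, which bind collagen and laminin, by 2.04 and 1.23. ANKRD1, CYR61 and TAGLN rose by 2.23, 1.31 and 2.02. PHLDA2, an imprinted gene that limits placental growth, fell by 2.98, from 48.9 ± 8.05 to 6.2 ± 0.706 CPM, and PAG8 fell by 2.21. IFNT2 rose by 2.20, HSD3B1 by 0.97 and H19 by 0.90, while GAPDH (-0.78), CDX2 (-0.41) and GATA2 (-0.28) fell.

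On day 2, 6127 of 16343 genes passed in edgeR, 2989 rising and 3138 falling. Beyond 2-fold, 956 rose and 372 fell. When all 18 libraries shared 1 fit 723 passed, 457 rising and 266 falling. That fit ended the day 2 calls of HAND1, ASCL2, PAG11, PAG8, IFNT2, HSD3B1, H19, CDX2, GATA2, GATA3, ELF5, KRT8, ANKRD1, TAGLN, COL3A1, SNAI2 and VIM (values of -3.05 to 2.52). GATA3 (-0.22), ELF5 (-0.71) and KRT8 (-0.20) were lower, but their calls ended without bTSC replicate 2 (-0.20, -0.60 and -0.16) and without 1 of the day 2 libraries (-0.15 and -0.13 for GATA3 and KRT8 without replicate 2, -0.52 for ELF5 without replicate 1). MKI67 was -0.15 and did not pass, and passed without bTSC replicate 2 (-0.26) or day 2 replicate 1 (-0.27).

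Matrix protease and integrin genes rose in 20 and fell in 1 of 21 cases on day 2, also adjusted over the list alone (adjusted p = 0.0268 in camera with an estimated correlation). Hippo pathway targets rose in 10 of 12 cases with 0 falling (11 and 0 adjusted over the list alone; camera adjusted p = 6.77e-10, adjusted p = 0.0268 with an estimated correlation). Mesenchyme and fibroblast markers rose in 5 and fell in 2 of 12 cases, also adjusted over the list alone (camera adjusted p = 1.52e-05, adjusted p = 0.0268 with an estimated correlation). Those rising were TAGLN, ACTA2, THY1, COL3A1 and COL5A1, which serve contraction, adhesion and matrix. SNAI2 (-3.07) and VIM (-0.50) fell, but the call of VIM ended without bTSC replicate 1 (-0.56) or 2 (-0.44), day 2 replicate 2 (-0.34) or either day 3 library (-0.50), in DESeq2 (-0.51) and with a stricter filter (-0.47). Immediate early genes rose in 9 and fell in 3 of 14 cases (9 and 4 adjusted over the list alone; camera adjusted p = 1.17e-07, adjusted p = 0.0273 with an estimated correlation). DNA replication genes fell in 15 and rose in 1 of 25 cases (18 and 1 adjusted over the list alone; camera adjusted p = 0.000628, adjusted p = 0.0596 with an estimated correlation).

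On day 3, BNIP3 (-5.11), H19 (-3.08), PHLDA2 (-4.32), ELF5 (-2.47), GATA2 (-1.04), CDX2 (-0.47) and GAPDH (-1.86) fell. HAND1 rose by 2.95, PAG11 by 1.75, PAG2 by 1.51, FOSL1, an AP-1 factor of invasive trophoblast, by 2.51, and the interferon-stimulated genes ISG15 and MX1 by 2.85 and 2.08. MKI67 was higher by 0.24, a call that ended without bTSC replicate 2 (0.13) or day 3 replicate 1 (0.20), and KRT8 (0.02) did not pass. In edgeR 7767 of 16343 genes passed, 4009 rising and 3758 falling, and 1884 passed with all 18 libraries in 1 fit, which ended the calls of CDX2 (-0.45), ELF5 (-2.46), MX1 (2.09) and MKI67 (0.25).

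Glycolysis and hypoxia genes fell in 16 and rose in 1 of 19 cases on day 3 (17 and 1 adjusted over the list alone; camera adjusted p = 5.22e-27, adjusted p = 0.0832 with an estimated correlation). Cholesterol synthesis genes fell in 18 and rose in 1 of 22 cases, also adjusted over the list alone (camera adjusted p = 8.56e-12, adjusted p = 0.0832 with an estimated correlation), with INSIG1 at -2.37 and HMGCS1 at -1.40. DNA replication genes rose in 13 and fell in 1 of 25 cases, also adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.111 with an estimated correlation), with MCM10 at 1.22. Interferon-stimulated genes rose in 12 of 16 cases with 0 falling (13 and 0 adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.176 with an estimated correlation).

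On days 4 and 5, HAND1 rose by 3.80 and 4.35, PAG11 by 2.31 and 2.55, PAG2 by 1.44 and 1.54, TIMP3 by 2.53 and 2.89, and ISG15 by 3.03 and 3.39. ASCL2 (-1.69 and -1.59), H19 (-3.16 and -2.68), CDX2 (-0.69 and -0.60) and BNIP3 (-4.42 and -4.78) fell, whereas KRT8 (-0.08 and 0.00) did not pass. In edgeR 7876 genes passed on day 4, 4142 rising and 3734 falling, and 7704 on day 5, 4034 rising and 3670 falling. With all 18 libraries in 1 fit, 2006 and 1926 passed. A change on any day was called for 10158 of 16343 genes in edgeR, or 2196 with all 18 libraries in 1 fit. All 20 ribosomal protein genes tested fell on each of days 2 to 5, also adjusted over the list alone (camera adjusted p of 1.19e-14, 4e-17, 3.59e-19 and 3.35e-17, and adjusted p of 0.108, 0.111, 0.124 and 0.137 with an estimated correlation). The 5 day comparisons share the same bTSC libraries, so their calls are not independent of each other.

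**Figure D4:**
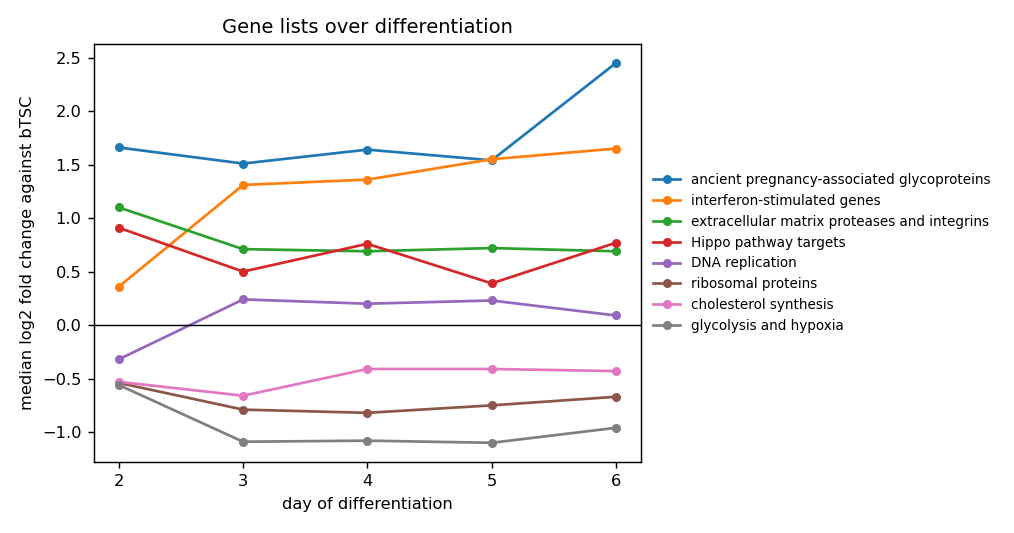
Median log2 fold change against bTSC (vertical axis) of 8 fixed gene lists on days 2 to 6 of differentiation (horizontal axis); each line is a list. Ancient pregnancy-associated glycoproteins had a median of 1.66 on day 2 and 2.45 on day 6, and glycolysis and hypoxia genes -0.56 and -0.96.

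The trend over days 2 to 6 was tested without the bTSC libraries. TKDP4 rose by 0.90 per day on the log2 scale (SE 0.0754), HAND1 by 0.61 (SE 0.0277; adjusted p = 3.88e-07 in edgeR) and PEG3, an imprinted zinc finger gene, by 0.38 (SE 0.0234; adjusted p = 4.84e-06 in edgeR). SLC45A2 rose by 0.84 per day and the Notch target HEYL by 0.66. The protease gene MMP9 (-0.34 per day), UBD (-0.89) and VIM (-0.38) fell. PAG11 rose by 0.28 per day, PAG12 by 0.29, PAG8 by 0.54 (0.34 in limma-voom) and TIMP3 by 0.27, while PAG2 (-0.02), CDX2 (-0.02), KRT8 (0.03), MKI67 (0.01) and H19 (-0.39) did not pass.

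The spread of the trend fit includes departures from a straight line, so genes that moved in a single step could miss its threshold. Day 6 against day 2 in the culture fit, a comparison chosen after the data were seen, called 6897 of 16343 genes in edgeR. For the trend, 2193 of 16174 genes passed in edgeR, 867 rising and 1326 falling. The count was 694 without day 2 replicate 2, 818 without day 2 replicate 1, 1356 and 1428 without day 5 replicate 1 and 2, and 1446 without day 6 replicate 1. It was 3378 in DESeq2 (1533 rising and 1845 falling) and 844 in limma-voom, where more genes rose (484) than fell (360). On days 3 to 6 only, a choice made after the data were seen, 2117 passed, 1206 rising and 911 falling, and 691 were called in the same direction in both. PIK3IP1 (-0.98 per day) and BNIP3 (-0.87) fell, but had slopes of 0.34 and 0.19 over days 3 to 6 and did not pass without day 2 replicate 1 (-0.85 and -0.71) or replicate 2 (-0.79 and -0.74). H19 and MKI67 also changed sign over days 3 to 6 and passed there (0.78 and -0.08), and UBD (-0.18) no longer passed there. PAG8 rose by 0.30 per day over those days, PAG12 by 0.44 and SLC45A2 by 1.27. In limma-voom PIK3IP1 (0.12), BNIP3 (-0.08) and UBD (-0.45) did not pass.

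Ancient pregnancy-associated glycoproteins rose in 3 of 5 cases over the days with 0 falling, also adjusted over the list alone (camera adjusted p = 0.000987, adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes rose in 6 of 16 cases with 0 falling (8 and 0 adjusted over the list alone; camera adjusted p = 0.000714, adjusted p = 0.815 with an estimated correlation). IFIH1, a sensor of double-stranded RNA, rose by 0.25 per day, and did not pass in limma-voom (0.18) or over days 3 to 6 (0.16). IFNT2 fell by 0.20 per day, and did not pass without day 2 replicate 1 (-0.17) or in limma-voom (-0.18). GATA6 (-0.30 per day) and IGF2 (-0.87) fell, and did not pass without day 2 replicate 1 (-0.21 and -0.62) or replicate 2 (-0.26 and -0.81). The call of IGF2 also ended without either day 4 library (-0.86 each), day 5 replicate 1 (-0.90) or 2 (-0.80) or day 6 replicate 2 (-0.85). Neither gene passed in limma-voom (-0.10 and -0.68) or over days 3 to 6 (-0.02 and -0.09).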

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

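The tests of remaining and of removed inner cell mass, of pathway spread, of single-library deviations and of scaling were chosen after related values had been seen. The other tests of explanations in this part were set beforehand.

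GATA3 stood out because its change against bTSC differed between day 2 (-0.22) and day 6 (0.21), by 0.43 (SE 0.0673; adjusted p = 2.85e-05 in edgeR), though each day's own call ended when some libraries were left out. H19 stood out in the same way, at 0.90 on day 2 and -0.74 on day 6, a difference of -1.63 (SE 0.171, adjusted p = 1.59e-07 in edgeR). Both genes were picked because their calls on these days had opposite signs and this difference passed. The p-values of the difference are thus part of the choice and no separate test.

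Oocyte transcripts were higher in blastocyst replicate 1 than in replicates 5 and 6. Over a further list of oocyte genes, 21 written down and 19 with at least 10 counts, the median log2 ratio of replicate 1 to the mean of the others was 2.72 (from CPM of each library's total, without TMM, with 0.1 added), and 18 of 19 were higher. In TMM-scaled CPM, CPEB1 was at 67.4 against 3.03 and 11.8 and NPM2 at 49.9 against 2.87 and 6.06. With the 3 libraries thinned to one total the median was 2.81. Because thinning keeps each gene's expected share of a library, the median could hardly have fallen, and this does not decide on the lower depth of replicate 1. Oocytes or arrested early embryos in that sample may account for the higher oocyte transcripts. GTSF1 (190.4 CPM against 141.9 in both others) and ZAR1L (70.1 against 32.7 and 35.9 CPM), 2 abundant members, were higher there too. However, GTSF1 was also at 266.4 to 347.9 CPM in trophectoderm. Without TMM, ZAR1L was at 16.33 to 34.12 CPM in trophectoderm and at 17.46 and 14.98 CPM in bTSC, so neither gene was particular to blastocysts. Slower loss of maternal RNA in developing embryos stays open, and no biological explanation was tested, since the labels give no group for it.

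POU5F1 was higher in trophectoderm than in blastocysts (1.56), and ranged from 1.17 to 1.89 with a library left out (adjusted p of 0.00484 to 0.0477 in edgeR). Inner cell mass cells left in the trophectoderm samples would bring their other transcripts. Of these, 10 inner cell mass genes had a median of -2.50, all 10 of them lower and 5 past the threshold. This test was chosen after related values had been seen, and the pluripotency genes ZFP42 and DPPA2 rose with POU5F1, so it cannot decide. Removal of the inner cell mass alone would raise trophectoderm genes alike, but KRT8 (1.93) and GATA2 (-0.89) lay 2.82 apart, although the call of GATA2 ended without blastocyst replicate 5 or 6. Thinning all libraries to one total left POU5F1 at 1.53. Thinning keeps the expected share of a well-counted gene, so this value could hardly have moved and does not decide on depth. A difference between the embryos or days of isolation, and a change in the trophectoderm cells themselves, may be behind the higher POU5F1 and were not tested.

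Embryo and culture profiles lay far apart, with 9308 genes between bTSC and trophectoderm. The count was 9040 after thinning, which argues against depth. A wrong scale factor moves all genes of a library alike, so as the whole cause it would not put genes beyond 2-fold on both sides. Yet 4256 genes were more than 2-fold higher and 4201 more than 2-fold lower, which argues against scaling as the whole cause. The near balance of these counts is no test, since TMM centres the fold changes (median of -0.0928 over all genes). Deviations of single embryo libraries had a median absolute correlation of 0.038 across genes with the culture minus embryo axis (genes are not independent replicates), but effects independent in each library would also give a value near 0, so this excludes none. A preparation difference common to all embryo libraries may remain and coincides with the groups. Whether whole pathways shifted together, as in a change of cell state, cannot be told apart from gene-by-gene differences: the SD within a list lay below the 5th percentile of 10000 matched random lists in 2 of 4 lists, mitosis (percentile 1.14) and ribosomal proteins (0), against 8.47 for DNA replication and 25.9 for oxidative phosphorylation. A biological difference between embryo and culture stays open.

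For trophectoderm against blastocysts, the 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 3206 genes, the highest other split gave 1, and 1 of the 10 splits gave as many as the real one, which is the real one itself.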

How the results depend on the processing

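The fits without 18S RNA, over days 3 to 6, and without genes high in 1 blastocyst library were chosen after the data were seen. With all 18 libraries in 1 fit, which takes its spread from embryos and cultures together, trophectoderm against blastocysts had 6158 genes, days 2 to 6 had 723, 1884, 2006, 1926 and 1898, and any day 2196. Requiring a 2-fold change in addition, which by construction leaves fewer genes, gave 1328, 2323, 2425, 2376 and 2299 on days 2 to 6 and 3349 for any day, and 0.25 per day in addition gave 778 for the trend (226 rising, 552 falling). The trend had 3378 genes in DESeq2 and 844 in limma-voom, where 57.3% rose in place of 39.5%; the cause was not tested. With each library left out, trophectoderm against blastocysts had 1752 to 3174 genes (lowest without blastocyst replicate 6) and the trend 694 to 2874 (lowest without day 2 replicate 2). The 99 list calls became 6 with an estimated correlation, 156 in fry's directional and 237 in its mixed test, which ask a different question; leaving out a library gave 96 to 103.

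Over days 3 to 6 the slope changed sign for PIK3IP1 (0.34), BNIP3 (0.19), H19 (0.78) and MKI67 (-0.08), where the day 2 libraries were left out. The trend over days 2 to 6 takes in the step from day 2 to day 3, at which 7039 genes passed in edgeR. H19 was at 997 CPM on day 2, 63.1 on day 3 and 321.4 on day 6, which is no straight line. In limma-voom PIK3IP1 changed sign too (0.12), and the cause of that was not tested. Of 228 gene calls in the text, 0 were lost with DESeq2's size factors, 3 in DESeq2, 11 in limma-voom (and PIK3IP1 in the trend, which changed sign there and did not pass) and 0 after thinning, 35 of 210 were lost with all 18 libraries in 1 fit, and 67 of 2272 in fits without 1 library. The other counts stayed within 1.5 times. bTSC against trophectoderm ranged from 6622 to 9511 with a library left out, bTSC against blastocysts from 6305 to 10285, and day 6 from 6134 to 7672. Without 18S RNA trophectoderm against blastocysts had 3219 genes, and without genes high in 1 blastocyst library 3340. The share of higher genes there was 57.2%, against 65.4% without 18S RNA but 50.2% in DESeq2 (2262 higher, 2245 lower), 52.3% in limma-voom, 53.1% with DESeq2's size factors and 53.5% after thinning. On days 3 to 6 it was 51.6 to 52.6%, and 48.9 to 49.6% with DESeq2's size factors.

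Replicate numbers did not pair the samples: same-numbered cultures had correlations of -0.053 to 0.062 between their deviations over 15 pairs of groups, 0 of them over 0.1. With the replicate number as a block, days 2 to 6 had 5976, 7620, 7725, 7557 and 7414 genes, any day 9987 and the trend 1611, and bTSC against trophectoderm 7484 against 9383 in the same fit without the block. In bTSC against trophectoderm that block made the calls of ELF5 (6.03) and CYP11A1 (1.65) and ended that of GATA3 (0.83), and it changed no other gene call in the text. Blastocyst numbers share only 1 with the other groups, so no block was fitted there. Depth sets the CPM that 3 counts come to, 0.262 to 0.459 in blastocysts and 0.0707 to 0.138 in trophectoderm. Depth alone did not set detection: blastocyst libraries held 18022 to 20193 genes with a count and the deeper trophectoderm libraries 16074 to 17112. In simulations with well-counted genes changed, edgeR recovered 7% of 2-fold changes in trophectoderm against blastocysts. It recovered 4% in the deeper bTSC and trophectoderm libraries, against 90% on day 6, so depth alone did not set these shares. The common biological coefficient of variation was 0.516 in the embryo fit and 0.0982 in the cultures.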

Other observations

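The comparisons of consecutive days and the genes in this part were chosen after the data were seen.

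Between day 2 and day 3, 7039 of 16343 genes passed in edgeR (3494 rising, 3545 falling), against 63 from day 3 to 4, 6 from day 4 to 5 and 296 from day 5 to 6 (222 rising, 74 falling). From day 2 to day 3, 9 of 27 lists passed in camera and 1 of them did so with an estimated correlation too. That was DNA replication, with 20 rising and 1 falling of 25 genes (21 and 1 adjusted over the list alone; camera adjusted p = 5.52e-12, adjusted p = 0.0108 with an estimated correlation). Glycolysis and hypoxia genes fell in 17 of 19 cases with 0 rising, also adjusted over the list alone (camera adjusted p = 1.53e-16, adjusted p = 0.196 with an estimated correlation). Ribosomal protein genes fell in 12 of 20 cases with 0 rising (13 and 0 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.57 with an estimated correlation). They had been listed beforehand with RNA quality in mind, which was not measured directly. From day 5 to day 6, 9 of 27 lists passed in camera and 0 with an estimated correlation. Of the 19 glycolysis and hypoxia genes 6 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 2.24e-14, adjusted p = 0.179 with an estimated correlation). Immediate early genes rose in 2 and fell in 4 of 14 cases (6 and 4 adjusted over the list alone). Camera with its preset correlation placed that list downward (camera adjusted p = 0.0119, adjusted p = 0.179 with an estimated correlation). Ribosomal proteins were shifted upward as a list (camera adjusted p = 0.00843, adjusted p = 0.697 with an estimated correlation), with 0 of 20 genes past the threshold, also adjusted over the list alone. The labels give no batch for the cultures.

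Imprinted genes fell in 7 and rose in 2 of 18 cases from day 2 to day 3, also adjusted over the list alone (camera adjusted p = 0.0343, adjusted p = 0.384 with an estimated correlation). From day 5 to day 6 they rose in 3 cases with 0 falling (4 and 0 adjusted over the list alone; camera adjusted p = 2.06e-05, adjusted p = 0.179 with an estimated correlation). H19 was at 534.7 ± 66.3 CPM in bTSC, 997 ± 37 on day 2, 63.1 on day 3, 59.9 on day 4, 83.4 on day 5 and 321.4 ± 74.7 on day 6 (n = 2 each). CDKN1C, an imprinted inhibitor of the cell cycle, went from 415.4 CPM in bTSC to 98.5 on day 3 and 397.4 on day 6, and was -0.06 on day 6 against bTSC, which did not pass. PEG3, also imprinted, took another course and was lowest in bTSC, at 165.4 CPM, with 280.8 on day 2, 391.3 on day 3 and 849.9 on day 6. Of other genes, CGA went from 188.3 CPM to 27.9 on day 3 and 57.8 on day 6. TKDP1, the most abundant of 3 trophoblast Kunitz domain genes, went from 7306 CPM in bTSC to 5567 on day 2 and 11340.0 on day 6.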
